A study of Mus musculus with 2 samples.

How the data were processed

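Choroid plexus of female C57BL/6 mice was measured by single-cell RNA sequencing at 3 and at 24 months of age. Per the labels' protocols, brains were perfused, the plexuses of both lateral ventricles and of the 4th ventricle were dissected, the tissue of 4 mice of 1 age was pooled before enzymatic digestion, and 1 droplet-based 10x Genomics 3′ library was made per age. The values are UMI counts (unique molecular identifiers, each standing for 1 captured transcript copy) per gene and barcode, which the authors deposited as whole numbers without normalization. The submitters' processing notes name Cell Ranger 4.0.0 and the mouse build mm10; the annotation and the way barcodes were called are not given in the sources used here. The deposited barcodes of both libraries held 500 or more UMIs, and none held more than 39809 UMIs, 5996 genes or 34.9% mitochondrial UMIs, so a filter had already been applied. Barcode suffixes have the form that Cell Ranger gives to aggregated libraries, and whether reads were subsampled to equal depth is not given in the sources used here. Genes are named by the symbols in the deposited files, of which 20104 of 20375 (98.7%) were found in GENCODE vM21. Coordinates are those of that annotation on mm10.

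Barcodes with fewer than 500 genes or more than 25% mitochondrial UMIs were removed, which left 8763 of 9154 barcodes at 3 months and 10073 of 10430 at 24 months. Scrublet, run per library in scanpy 1.11.5, marked 20 and 11 barcodes (0.218% and 0.105%) with its automatic threshold, which did not work. The fallback chosen before the data were examined was used instead: the barcodes with the highest scores were removed up to 0.8% per 1000 barcodes, which were 670 and 870 barcodes, 640 and 843 of them among those that had passed the filter. This left 8123 cells at 3 months and 9230 cells at 24 months. Both libraries were clustered together without integration, from 2000 variable genes, 30 principal components and 20 neighbours, with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 1.0. Of 16 marker sets fixed before the data were examined, all but the proliferating one could name a cluster. A cluster took its name from the set with the most markers detected. A marker had to be in 25% or more of the cluster's cells at a mean at least 2 times that of other clusters. A name needed at least 3 such markers. A cluster stayed unnamed with a median depth under 33.3% of its library's and none of the set's markers in its top 10 genes. The same held when another set had more markers among those 10 genes. A cluster in which a second set had at least 5 markers and at least 75% as many as the first was kept apart as mixed; the markers had been fixed but these scoring thresholds were set on these data. The neutrophil, mast cell, erythroid, ependymal, astroglial, oligodendroglial and neuronal sets named no cluster. Rebuilt cell names may differ from those of the study.

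UMIs were summed per library over the cells of each class with at least 100 cells in each library and expressed as CPM, counts per 1000000 UMIs of the class total. Cells are not replicates, and with 1 library per age no test was made and no p-value is given. Each gene has its CPM at both ages and their ratio with an exact conditional binomial 95% interval; summed CPM has exact Poisson intervals and shares of cells have exact Clopper-Pearson intervals. All of these cover counting error only. A UMI count of 0 was given a floor of 3 counts over the class. Log2 ratios are of CPM plus a pseudocount of 1 CPM, which understates the differences of low genes, for genes with at least 50 UMIs over both libraries. For each of 25 gene lists fixed before the data were examined, the median log2 ratio is given with an interval from 1000 Poisson draws and with its percentile among 10000 random lists of the same size drawn from the 100 genes nearest in mean expression to each member. The percentile describes these libraries and is not a test. A list is described as standing apart below the 5th or above the 95th percentile. A member counts as higher or lower when its CPM ratio was at least 1.25 either way and its interval excluded 1, which is a rule of size.

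The genes named were chosen by a rule fixed before the data were examined. In epithelial-like cells they are the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM in 1 library, an interval that excluded 1 and the same direction under every scaling tried. In other classes they are the 6 highest and 6 lowest with at least 100 CPM, without genes whose level in the class was below 10% of that in epithelial-like cells. Predicted genes, Xist, haemoglobin, mitochondrial and ribosomal protein genes were left out of this ranking. In each list that stood apart, up to 4 members with the largest ratios among those with at least 20 CPM are named, and 13 epithelial genes are always given. Genes or cells chosen after their values were seen are said to be so. Shares of cells with a UMI were compared after drawing 5000 UMIs per epithelial-like cell and 1500 per cell of other classes, without shallower cells.

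The ratio and list steps were tested on simulated data with the class totals of these libraries. Counts were Poisson draws for each gene on its own. Differences between mice or preparations and genes that vary together were not simulated, so these figures cover counting error only. Among 13487 epithelial genes, the size rule called 46.5% of genes made 1.25-fold different, 93.9% at 1.5-fold, 100% at 2-fold and 1.04% of unchanged genes. Among 2722 macrophage genes it called 30.9%, 60.0% and 98.1% at those sizes and 2.76% of unchanged genes. Of 200 unchanged lists of 25 genes, 12.5% in the epithelial and 10.5% in the macrophage simulation fell below the 5th or above the 95th percentile, close to the 10% such limits allow, and all lists made 1.5-fold different lay above it.

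Each result was recomputed with no filter on barcodes, with a stricter one (at least 1000 genes and at most 10% mitochondrial UMIs), without removing doublets, at a Leiden resolution of 0.5, with each library clustered on its own, with edgeR's TMM factors (edgeR 4.0.16), with DESeq2's median of ratios (DESeq2 1.42.0), with CPM without Ttr and mitochondrially encoded genes, with the mean of per-cell CPM, with thinned cells, with no gene filter, with at least 500 UMIs per gene, with a pseudocount of 10 CPM, and without genes 10 times higher in another class. Other software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3. Sequencing reads were not analysed here.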

Results

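The choroid plexus, the secretory epithelium of the brain ventricles with its vascular stroma, was profiled by droplet-based single-cell RNA sequencing in female C57BL/6 mice aged 3 and 24 months, to compare the young with the aged tissue. Each age was 1 library made from the pooled lateral and 4th ventricle plexuses of 4 mice. The comparison therefore set 1 library against 1 library; it had no replicate check and nothing was tested. The 3 month library held 9154 barcodes and 111403078 UMIs, with medians of 10823 UMIs and 2697 genes per barcode. The 24 month library held 10430 barcodes and 116777113 UMIs, with medians of 10739 UMIs and 2665.5 genes. After filtering and doublet removal, 8123 cells were kept at 3 months and 9230 at 24 months. Values are given with 3 months first, and ranges in brackets are 95% intervals for counting error only.

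The first question was which cells made up the tissue at each age. Epithelial-like cells, marked by transthyretin (Ttr) and the folate receptor Folr1, were 67.1% (66.1 to 68.2) of kept cells at 3 months and 67.4% (66.4 to 68.4) at 24 months. B cells and T cells were more frequent at 24 months, and NK cells less frequent. B or plasma cell-like cells were 4 cells at 3 months and 41 cells at 24 months, 0.0492% (0.0134 to 0.126) and 0.444% (0.319 to 0.602), a ratio of 9.02 (3.27 to 34.7). T or NK cell-like cells were 1.24% (1.01 to 1.51) and 2.38% (2.08 to 2.72). The 2 clusters of this class came mostly from different libraries. The cluster led by T cell receptor genes had 41 and 203 cells, a share ratio of 4.36 (3.10 to 6.25). The cluster led by granzyme and NK receptor genes had 60 and 17 cells, a ratio of 0.249 (0.136 to 0.433). Macrophage-like cells were 2.73% (2.39 to 3.11) and 2.21% (1.92 to 2.53). Monocyte or dendritic cell-like cells were 0.603% (0.447 to 0.797) and 0.390% (0.273 to 0.540). The vascular classes were less frequent at 24 months. Endothelial-like cells were 9.54% (8.91 to 10.2) and 6.46% (5.96 to 6.98). Mural-like cells, the pericytes and smooth muscle of the vessels, were 2.50% (2.17 to 2.86) and 1.19% (0.981 to 1.43). Mesenchymal-like cells, the fibroblasts of the stroma, were 14.2% (13.5 to 15.01) and 17.4% (16.7 to 18.2). A cluster with endothelial and mural markers, kept out of both classes by a threshold set after seeing the data, held 1.80% (1.52 to 2.11) and 1.28% (1.06 to 1.53) of cells. A cluster that met no marker rule held 0.160% and 0.802%. The stricter filter, whose limit of 10% mitochondrial UMIs lay below the epithelial medians of 12.4% and 13.5%, turned the epithelial difference from 0.257 to −6.28 percentage points. It moved those of endothelial-like cells from −3.08 to −5.00, mesenchymal-like from 3.21 to 6.40, T or NK from 1.14 to 0.533 and B or plasma from 0.395 to 0.659. Under this filter a cluster of 271 and 457 cells with 9 mesenchymal markers lost its name and the endothelial and mural cluster, 137 and 108 cells, was named endothelial-like, so these 2 classes also changed in membership. Clustering each library on its own gave a mesenchymal difference of −4.80 points, because a 24 month cluster of 742 cells with 8 mesenchymal markers then lost its name while its 3 month counterpart of 687 cells kept it.

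**Figure D1:**
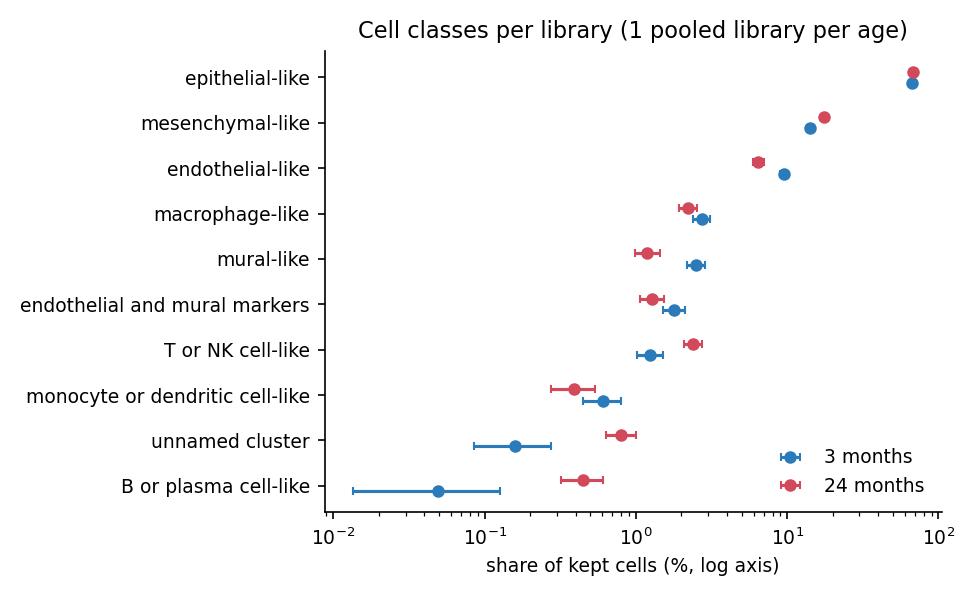
Share of kept cells in each class (percent, log axis) in the 3 month (blue) and 24 month (red) library, with points for the shares and bars for exact binomial 95% intervals. Epithelial-like cells sat at 67.1% and 67.4%, B or plasma cell-like cells at 0.0492% and 0.444%, and endothelial-like cells at 9.54% and 6.46%.

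The main comparison was of gene expression in epithelial-like cells, with 5454 cells and 86985360 UMIs at 3 months and 6221 cells and 89956670 UMIs at 24 months, over 13492 genes. Type I interferon response genes were higher at 24 months as a group. All 27 measured members were higher by the size rule, and the median log2 ratio was 1.49 (1.34 to 1.68), at the 100th percentile of matched random lists. Ifit1, an antiviral RNA-binding protein encoded on chromosome 19 (34640871 to 34650009, mm10), was at 1.196 and 34.3 CPM, 28.7-fold (23.6 to 35.2) higher. The ubiquitin-like modifier Isg15 was at 0.747 and 22.5 CPM, 30.1-fold (23.5 to 39.1) higher. Ifi27l2a was 10.8-fold (10.3 to 11.4) higher and Rtp4 10.7-fold (9.29 to 12.4) higher. Irf7, a transcription factor of the interferon response, was 5.29-fold (4.47 to 6.29) higher. The membrane proteins Ifitm3, at 54.3 and 349 CPM, and Bst2 (tetherin), at 139 and 587 CPM, were 6.43-fold (6.24 to 6.63) and 4.24-fold (4.15 to 4.32) higher. Ifi27, already at 650.03 CPM at 3 months, was 1.55-fold (1.54 to 1.57) higher. Genes of MHC class I and peptide loading were higher with a median of 0.61 (0.54 to 0.69), with 12 higher and 1 lower of 17. H2-T23 was 2.50-fold, H2-D1 2.32-fold, the light chain B2m 2.16-fold (2.10 to 2.22) and H2-K1 1.77-fold (1.71 to 1.84) higher. Epithelial clusters 1, 6 and 7 were held mostly by 1 library, cluster 1 by 3 months and clusters 6 and 7 by 24 months. Cluster 6 was itself led by Spink8 and interferon genes and cluster 7 by heat shock genes. Without these 3 clusters, left out after seeing the data, the interferon median was 0.58, still at the 100th percentile with 18 of 23 members higher. Ifi27l2a was then at a log2 ratio of 1.72 in place of 3.36, Ifitm3 at 1.72 in place of 2.66, Irf7 at 0.74 in place of 1.92 and Bst2 at 1.28 in place of 2.07. Most members of these lists were low, so a pseudocount of 10 CPM gave medians of 0.61 for the interferon and 0.19 for the MHC class I list. Leaving out genes 10 times higher in another class gave 0.16 for MHC class I.

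The interferon genes were higher across the epithelial cells and not only in a few of them, with the highest level in cluster 6. From 5000 UMIs drawn per cell, without 608 and 535 shallower cells, the median was 5 interferon-list UMIs per cell at 3 months and 9 at 24 months. The 90th percentile was 9 and 29. Above the 99th percentile of the 3 month cells lay 1.01% of those cells and 30.3% (29.1 to 31.5) of 24 month cells. The limit lay within a run of cells, with 133 and 785 cells within 3 UMIs of it. At 5000 UMIs per cell, these counts cannot tell a range from a separate group of cells. The list was higher at 24 months in each of the 6 epithelial clusters, with medians from 0.78 to 1.59. They rest on the 14 to 25 members with at least 50 UMIs in the cluster, a limit reachable by 24 month counts alone. At 24 months the list summed to 5557 CPM in cluster 6, with 1287 cells, and to 1621 to 2066 CPM in the other clusters. A UMI of Ifit1 was found in 1.12% (0.857 to 1.43) and 17.9% (16.9 to 18.9) of epithelial-like cells at median depths of 17170 and 14823 UMIs, or 0.413% and 10.1% of thinned cells. In endothelial-like cells, at median depths of 2281 and 2264 UMIs, Ifit1 was found in 5.42% and 8.22%, or 2.95% and 5.34% of thinned cells, so this class gives no background for it. Bst2 was found in 60.3% and 84.6% of epithelial-like cells, or 36.8% and 71.4% of thinned cells. In mesenchymal-like cells it was found in 31.5% and 33.4%, or 14.0% and 18.0% of thinned ones, at median depths of 3913 and 3144 UMIs.

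**Figure D2:**
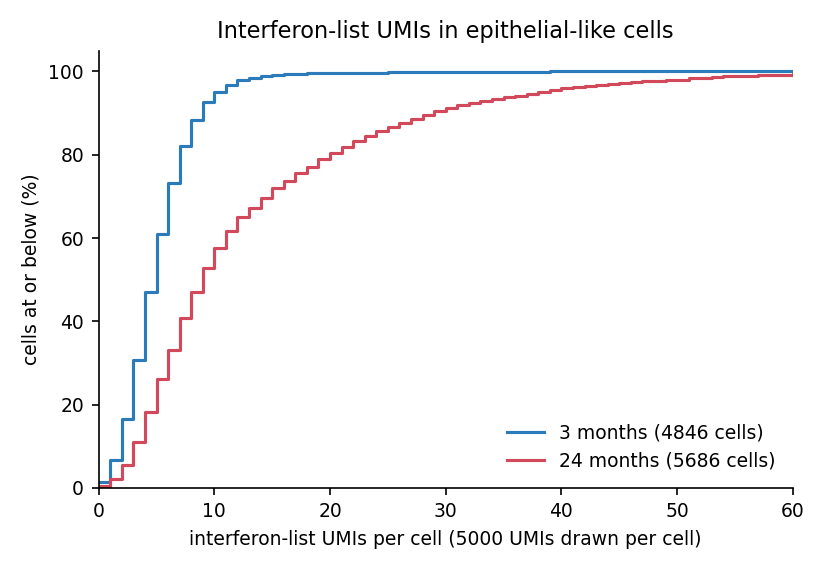
Cumulative share of epithelial-like cells (percent, vertical axis) by the number of interferon-list UMIs in a cell after drawing 5000 UMIs per cell (horizontal axis), for 4846 cells at 3 months (blue) and 5686 cells at 24 months (red). The 24 month curve lies to the right over the plotted range, with medians of 5 and 9 UMIs and 90th percentiles of 9 and 29.

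The other epithelial groups differed less. Stress-response genes of the immediate early and heat shock list were higher, with a median of 0.55 (0.54 to 0.58), 15 higher and none lower of 23. The AP-1 subunits Fos, 2.16-fold (2.12 to 2.21), and Fosb, 2.03-fold, led it with Ier2, 2.01-fold, and the phosphatase Dusp1, 1.82-fold. Without clusters 1, 6 and 7 its median was 0.20. The list also stood apart in mesenchymal-like, endothelial-like and mural-like cells, at 0.21, 0.22 and 0.16. It did not in macrophage-like or T or NK cell-like cells. Each age was 1 preparation, so an effect of preparation on this list is not told apart from age. Lysosomal genes had a median of 0.14 (0.13 to 0.17), 3 higher of 24, with the glucosidase Gaa 1.32-fold, cathepsin D (Ctsd) 1.27-fold and Scarb2 1.26-fold higher. Complement and acute phase genes had a median of 0.25 (0.18 to 0.42), 4 higher of 9, with the protease inhibitor A2m 2.24-fold (2.19 to 2.28) higher; clusterin (Clu), at 1.12-fold, was short of the size rule. That median was 0.66 with the stricter filter and 0.16 with a pseudocount of 10 CPM. Genes of endoplasmic reticulum folding and stress were lower, with a median of −0.26 (−0.28 to −0.24) and 8 of 20 lower. Creld2 was at 0.538-fold (0.512 to 0.565), Manf, at 503 and 325 CPM, 0.646-fold (0.636 to 0.656), Herpud1 0.644-fold and the transcription factor Xbp1 0.723-fold. Motile cilia genes were lower, with a median of −0.23 (−0.28 to −0.22) and 8 of 26 lower. The radial spoke gene Rsph1 was at 0.699-fold (0.678 to 0.720), Ak7 0.661-fold, Pifo 0.705-fold and 1110017D15Rik 0.627-fold. Cholesterol synthesis genes had a median of −0.15 (−0.18 to −0.13), at percentile 2.13, with 3 of 19 lower, among them Lss 0.678-fold and Fdps 0.769-fold. The median was −0.07 with thinned cells and −0.23 without clusters 1, 6 and 7, there at percentile 0.0900 with 6 of 19 lower. Nuclear-encoded genes of oxidative phosphorylation had a median of −0.13 (−0.14 to −0.13), at percentile 0, with none of 74 past the size rule and Ndufv2 at 0.820-fold and Sdhc at 0.822-fold. Mitochondrially encoded genes had a median of 0.07 (0.07 to 0.08), with none of 13 higher and mt-Nd6 lower at 0.772-fold. That median was 0.13 without clusters 1, 6 and 7 and 0.04 with the stricter filter.

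Hallmark functions of the epithelium were close to level between the ages. Secreted and hallmark products had a median of −0.02 (−0.03 to −0.01), at percentile 61.1, and ion and water transport genes −0.03 (−0.05 to −0.01), at percentile 87.3; ribosomal protein genes had a median of −0.01 (−0.02 to −0.01), at percentile 99.7; the 3 medians turned positive, to between 0.01 and 0.03, under TMM factors, the median of ratios and CPM without Ttr and mitochondrial genes. Of the 20 secreted products, the prolactin receptor Prlr was 1.31-fold (1.30 to 1.32) and Vegfa 1.26-fold higher and Calml4 was at 0.720-fold. Of the 28 transport genes 1 was higher, Slc2a12 at 1.26-fold, and 1 lower, Abca8a at 0.708-fold, from a level under 20 CPM. Tight and adherens junction genes had a median of 0.04 (0.01 to 0.08), at percentile 98.4, with 2 of 20 higher and 1 lower. That median was 0.08 for the mean of per-cell CPM and 0.02 without clusters 1, 6 and 7. The cadherin Cdh1, a member chosen after its values were seen, had a UMI in 2.97% (2.54 to 3.46) and 17.1% (16.2 to 18.1) of epithelial-like cells, or 1.03% and 6.74% of thinned cells. As background, it was found in 0.519% and 0.745% of mesenchymal-like cells, or 0.264% and 0.511% of thinned ones. Thinned mesenchymal-like cells held 1500 UMIs against 5000 in epithelial-like cells, so the excess over this background was not measured. Ttr, the thyroid hormone carrier on chromosome 18 (20665280 to 20674321), took 26.0% and 26.5% of epithelial UMIs (1.02-fold). Klotho (Kl) was at 0.997-fold (0.988 to 1.01), autotaxin (Enpp2) at 0.989-fold (0.987 to 0.992) and Folr1 at 0.983-fold (0.974 to 0.992). Each of these 3 lay above 1 under TMM factors, the median of ratios and CPM without Ttr and mitochondrial genes. Igf2 was at 0.913-fold (0.844 to 0.988) and the water channel Aqp1 at 0.850-fold (0.828 to 0.872). Of the senescence genes, Cdkn1a was at 1.06-fold (0.983 to 1.14). It had a UMI in 18.0% and 16.5% of epithelial-like cells and 7.12% and 7.58% of thinned ones, against 41.8% and 51.3% of mesenchymal-like cells and 22.6% and 32.9% of thinned ones. Cdkn2a had 1 and 3 UMIs, too few for a fold. The senescence and inflammatory mediator list had a median of 0.08 (0.02 to 0.12), at percentile 97.8, with 5 higher and 3 lower of 19 and the adhesion molecule Vcam1 1.31-fold higher. Without clusters 1, 6 and 7 it was 0.02 at percentile 91.1, inside the range of matched lists, and with the stricter filter it was 0.25.

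**Figure D3:**
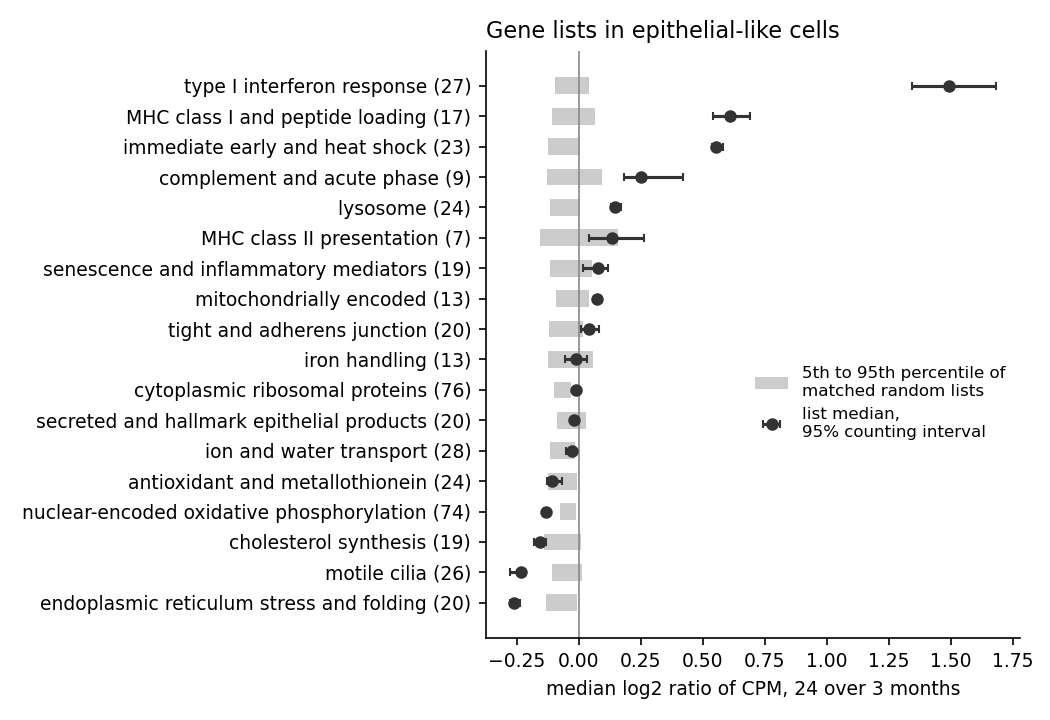
Median log2 ratio of CPM (24 over 3 months, horizontal axis) of each gene list in epithelial-like cells, with the number of measured genes in brackets, 95% counting intervals as bars and the 5th to 95th percentile of matched random lists in grey. The interferon list stood at 1.49 and MHC class I at 0.61, endoplasmic reticulum folding at −0.26 and motile cilia at −0.23, and the secreted, transport and ribosomal lists at −0.02, −0.03 and −0.01, which turned positive under TMM factors, the median of ratios and CPM without Ttr and mitochondrial genes.

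The single gene that differed most in epithelial-like cells was Spink8, a serine protease inhibitor of the Kazal family on chromosome 9 (109812280 to 109826633). It had 119 UMIs at 3 months and 30627 at 24 months, 1.37 and 340.5 CPM, a ratio of 249 (208 to 301). Its log2 ratio was 7.17, against 5.21 without clusters 1, 6 and 7, of which cluster 6 was led by Spink8, and 4.95 with a pseudocount of 10 CPM. A Spink8 UMI was found in 0.843% (0.618 to 1.12) and 30.5% (29.3 to 31.6) of epithelial-like cells, or 0.495% and 21.5% of thinned cells. As background, 0 of 1156 mesenchymal-like cells had one at 3 months, which allows up to 0.319% of cells. At 24 months it was found in 5.53% (4.46 to 6.76), and thinned cells gave 0% and 2.94%, at median depths of 3913 and 3144 UMIs. These cells were shallower and were thinned to fewer UMIs than epithelial-like cells, so the excess over this background was not measured. At 24 months Spink8 was at 1298 CPM in cluster 6, and at 25.9, 70.9 and 189 CPM in clusters 0, 2 and 8. It reached 35.5 CPM in B or plasma cell-like cells, so RNA carried over is not told apart in cluster 0. Other genes higher at 24 months were the carboxypeptidase-like Cpxm2, at 12.96 and 62.9 CPM and 4.85-fold (4.55 to 5.18), the growth factor midkine (Mdk), 2.63-fold (2.53 to 2.72), and the secreted glycoprotein Lgals3bp, 2.56-fold (2.50 to 2.63). Ly6e was 2.49-fold (2.41 to 2.58) and carboxypeptidase E (Cpe) 2.36-fold (2.28 to 2.45) higher. Cox8b, a subunit of cytochrome c oxidase, was at 262 and 590.1 CPM, 2.25-fold (2.22 to 2.29) higher. Lower at 24 months were the beta-defensin Defb11, at 65.0 and 35.5 CPM and 0.546-fold (0.523 to 0.570), insulin 2 (Ins2), 0.596-fold (0.569 to 0.624), and the calmodulin-binding Pcp4, 0.628-fold (0.612 to 0.643). Cyclin D2 (Ccnd2) was at 0.657-fold (0.644 to 0.670), Crip2 at 0.670-fold, alpha-tubulin Tuba1a at 0.680-fold, Serpinb1b at 0.689-fold and Tmsb10 at 0.696-fold.

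Mesenchymal-like cells, 1156 and 1610 cells with 4632151 and 5283709 UMIs over 9882 genes, had lower matrix genes and higher apolipoprotein D at 24 months. Apod, a lipid carrier, was at 1894 and 8447 CPM, 4.46-fold (4.36 to 4.56) higher. The glycine receptor subunit Glra3 was at 28.5 and 237 CPM, 8.32-fold (6.95 to 10.0) higher. The Hedgehog receptor Ptch1 was 3.403-fold (2.83 to 4.12) and Mpzl2 2.37-fold (2.04 to 2.77) higher. Collagen and matrix genes had a median of −0.39 (−0.49 to −0.29), at percentile 0, with 16 of 30 lower and 2 higher. Col3a1 was at 99.5 and 30.5 CPM, 0.306-fold (0.254 to 0.367). Col5a2 was at 0.450-fold, Col1a2, at 609 and 284 CPM, 0.467-fold (0.438 to 0.497), and Sparc 0.505-fold. Ccnd2 was at 0.216-fold (0.189 to 0.247), the noncoding RNA Meg3 at 0.220-fold, myosin light chain Myl9 at 0.433-fold and Mxd4 at 0.457-fold. Lower too was the growth factor pleiotrophin (Ptn), at 2329 and 1104 CPM and 0.474-fold (0.459 to 0.489). Folding genes of the endoplasmic reticulum were lower, with a median of −0.36 (−0.42 to −0.31) and 12 of 20 lower. Creld2 was at 0.467-fold, Pdia6 0.576-fold and Manf 0.594-fold. Cholesterol synthesis genes had a median of −0.44 (−0.51 to −0.37), 12 of 19 lower, with Msmo1 0.572-fold and Fdps 0.604-fold. Interferon genes had a median of 0.30 (0.21 to 0.41), 11 of 27 higher and none lower, including Trim30a 2.82-fold, Ifit3 1.80-fold and Irf7 1.64-fold. That median was 0.19 for genes with at least 500 UMIs. MHC class I genes had a median of 0.32 (0.19 to 0.38), 7 of 16 higher, including H2-Q7 3.48-fold and H2-K1 1.49-fold. Of the senescence and inflammatory mediators, 10 of 21 were higher and 3 lower, with a median of 0.18 (0.12 to 0.37). The chemokines Cxcl10 and Ccl2 were 1.79-fold and 1.56-fold and Cdkn1a 1.56-fold higher, and Vcam1 was at 0.604-fold. With thinned cells that median was 0.43. Immediate early and heat shock genes had a median of 0.21 (0.14 to 0.26), with Hspa1a 1.54-fold and Nr4a1 1.51-fold higher. Cluster 5, 648 and 713 cells led by Crabp1 and Coch with none of the fixed markers among its top 10 genes, was the less certain part of this class. Without it, left out after seeing the data, the collagen median was −0.54, the Glra3 log2 ratio was 5.45 in place of 3.01, that of Ptn −1.71 in place of −1.08. The senescence list, then at 0.09 and percentile 91.4, and the oxidative phosphorylation list, at −0.06 in place of −0.12, no longer stood apart. Immunoglobulin genes met the naming rule from few cells. At 24 months 1 cell held 3333 of 3614 Igkc and 1096 of 1228 Ighm UMIs, against 3 and 1 UMIs over all cells at 3 months. Without that cell the ratios were 82.3 (27.9 to 401) and 116 (20.5 to 4614).

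Endothelial-like cells, 775 and 596 cells with 1994562 and 1632911 UMIs over 6750 genes, had higher MHC class I genes and lower oxidative phosphorylation genes at 24 months. H2-Q7 was at 58.2 and 335 CPM, 5.76-fold (4.71 to 7.10) higher, H2-Q6 4.36-fold (3.395 to 5.65) and H2-T22 2.47-fold (1.92 to 3.20). These belong to a family of near-identical genes, so their split is uncertain. The MHC class I list had a median of 0.20 (0.12 to 0.36), with 7 of 17 higher and 2 lower. The interferon list had a median of 0.20 (0.03 to 0.28), with 5 of 24 higher, including Ifit1 1.87-fold and Rsad2 1.58-fold. For genes with at least 500 UMIs the MHC class I median was 0.33. The hypoxia-inducible lipid droplet gene Hilpda was 3.02-fold (2.55 to 3.60) higher, the noncoding RNA Neat1 2.23-fold (1.99 to 2.50) and the growth factor Hbegf, at 881 and 1893 CPM, 2.15-fold (2.02 to 2.28). Aqp1 was at 0.468-fold (0.363 to 0.599), Cacybp at 0.489-fold, the matrix protein Fbln2 at 0.521-fold and the mitochondrial protein Chchd10 at 0.532-fold. Carried-over epithelial RNA was also lower in this class, with epithelial markers at 28188 and 19884 CPM and Ttr at 25618 and 17750 CPM. Chchd10, at 226 and 120 CPM here and 1724 CPM in epithelial-like cells, is not told apart from it. Thrombospondin 1 (Thbs1) was at 0.541-fold and the clock-controlled transcription factor Dbp at 0.545-fold (0.441 to 0.671). With thinned cells the log2 ratios of Aqp1 and Dbp were −0.55 and −0.54 in place of −1.08 and −0.87, and with the stricter filter that of Thbs1 was −0.49 in place of −0.88. Oxidative phosphorylation genes had a median of −0.23 (−0.28 to −0.19), 21 of 73 lower and none higher, with Atp5k 0.627-fold and Ndufa3 0.677-fold, and the part due to the lower epithelial RNA was not tested. Mitochondrially encoded genes had a median of −0.14 (−0.15 to −0.09). These medians were −0.10 and −0.07 with the stricter filter. Collagen and matrix genes had a median of −0.30 (−0.40 to −0.21), 6 of 16 lower, with Col15a1 0.559-fold. Folding genes had a median of −0.11 (−0.23 to −0.05), 5 of 20 lower, with Pdia6 0.613-fold, and −0.05 with thinned cells. Immediate early and heat shock genes were higher, 9 of 23, with a median of 0.22 (0.17 to 0.26), Hspa1a 1.78-fold and Nr4a1 1.72-fold. The senescence list had a median of 0.15 (0.07 to 0.25), 3 of 15 higher, with Cxcl10 2.87-fold. Complement was at 0.30 (0.15 to 0.44) over 4 genes and MHC class II 0.32 (0.06 to 0.55) over 4 genes. With the stricter filter these 3 medians were 0.04, 0.08 and 0.18. Complement was at 0.03 with thinned cells, and MHC class II at 0.78 without doublet removal. The fenestration and angiogenesis list and the adhesion list lay among their matched lists, with medians of 0.06 and 0.02 at percentiles 51.9 and 71.8.

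In mural-like cells, 203 and 110 cells with 469979 and 266991 UMIs over 2402 genes, interferon and MHC class I genes were again higher, though few were measured. Of these, 3 of 4 interferon genes were higher, with a median of 0.63 (0.35 to 0.95), among them Bst2 2.82-fold (1.56 to 5.20) and Isg15 1.65-fold, and 2 of 7 MHC class I genes were higher, with a median of 0.40 (0.13 to 0.67). The hormone stanniocalcin 1 (Stc1) was 2.37-fold (1.65 to 3.42), Neat1 2.22-fold (1.58 to 3.12), Dpep1 2.25-fold (1.34 to 3.79) higher. Apod was 2.38-fold (1.46 to 3.92) higher, but 14 of its 42 UMIs at 24 months were in 1 cell, without which it was 1.60-fold (0.926 to 2.76), an interval that includes 1. Its log2 ratio was 2.87 with the stricter filter in place of 1.24. Apod and Dpep1 reached 8447 and 883 CPM in mesenchymal-like cells, so RNA carried over from that class is not told apart in their values. Col1a2 was at 0.263-fold (0.135 to 0.474), Sned1 at 0.276-fold and the neurotrophin Bdnf, at 281 and 89.9 CPM, at 0.320-fold (0.198 to 0.497). Col1a2 and Sned1 reached 609 and 314 CPM in mesenchymal-like cells, where Col1a2 was lower at 24 months too. RNA carried over from that class is not told apart in these 2 values either. Tnpo1 was at 0.359-fold, and Rab5c and Sin3b each at 0.403-fold. Spp1 was 3.61-fold higher, but 35 of its 41 UMIs at 24 months were in 1 cell, without which it was at 0.534-fold (0.175 to 1.38). The lysosomal list had a median of 0.18, immediate early and heat shock 0.16 and antioxidant 0.16; with thinned cells the lysosomal and antioxidant medians were 0.03 and 0.05. The antioxidant median was 0.34 with the stricter filter and 0.35 with no gene filter, and the immediate early median 0.24 with the stricter filter and 0.10 under TMM factors. Oxidative phosphorylation had a median of −0.08 (−0.11 to 0.03), which turned to 0.07 for genes with at least 500 UMIs.

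Macrophage-like cells, 222 and 204 cells with 716570 and 592826 UMIs over 2722 genes, differed most in 2 chemokines. Cxcl13, a B cell attractant on chromosome 5 (95956951 to 95961068), had no UMI in 222 cells at 3 months. At 24 months it had 540 UMIs in 48 of 204 cells, 218-fold higher against a floor of 3 counts over the class. The lower bound of its counting interval was 176-fold. Ccl8 had 8 UMIs in 6 cells and 322 UMIs in 38 cells, 48.7-fold (24.4 to 114) higher, and 19 cells at 24 months had both. The adhesion molecule Vcam1, at 382 and 997 CPM, was 2.61-fold (2.26 to 3.02), complement C4b 4.61-fold (2.62 to 8.56) and the protein C receptor Procr 2.81-fold (1.92 to 4.18) higher. Procr was at a log2 ratio of 2.39 with the stricter filter in place of 1.47. At 3 months 18 of its 40 UMIs were in 1 cell, without which it was at 31.0 in place of 55.8 CPM. Apod was 12.9-fold (5.61 to 36.4) higher with 34 of 64 UMIs in 1 cell, and 6.08-fold (2.49 to 17.9) without that cell. It was at 1894 and 8447 CPM in mesenchymal-like cells, so RNA carried over from that class is not told apart. MHC class II genes had a median of 0.41 (0.36 to 0.47), 5 of 8 higher, with H2-Eb1 1.49-fold, H2-Ab1 1.41-fold and H2-Aa 1.37-fold. Complement genes had a median of 0.41 (−0.08 to 0.85), 2 of 5 higher. Oxidative phosphorylation genes had a median of −0.18 (−0.26 to −0.10), 11 of 69 lower, with Ndufb6 0.459-fold and Uqcrfs1 0.530-fold, and −0.12 with the stricter filter. Epithelial markers in this class were lower too, at 28278 and 24547 CPM, and their part in this median was not tested. The transcription factor Maf was at 0.498-fold (0.356 to 0.689), Filip1l at 0.387-fold and the kinase Plk2 at 0.489-fold. Ldhb, at 937 CPM in epithelial-like cells against 105 and 52.3 CPM here, was at 0.4996-fold. Endothelin 1 (Edn1) was at 0.356-fold. Of its 30 UMIs at 24 months 11 were in 1 cell, without which it was at 0.226-fold (0.131 to 0.372). Interferon beta (Ifnb1) was at 0.329-fold (0.208 to 0.503), with 13 of 28 UMIs at 24 months in 1 cell, and its log2 ratio of −1.59 turned to 0.18 with the stricter filter. The interferon list was level in this class, at 0.03 (−0.13 to 0.15) and percentile 84.1, and the lipid-associated macrophage list was at 0.01 and percentile 64.5. The border macrophage residency list had a median of 0.16 (0.01 to 0.28), with 1 of 9 higher and 2 lower, and was at 0.28 with the stricter filter. MHC class I was at 0.12 with none of 13 past the size rule, and iron handling 0.19 with 1 of 6 higher, which was 0.03 with thinned cells. Ribosomal protein genes were at −0.03, which TMM factors and the median of ratios turned to 0.01 and 0.02. The 3 cholesterol genes measured were at 0.57, which no gene filter turned to −0.13.

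In the T or NK cell-like class, 101 and 220 cells with 262414 and 529132 UMIs over 2103 genes, the T-led cluster had 41 and 203 cells and the NK-led cluster 60 and 17, and values were not taken apart by cluster. Higher at 24 months were Tnfsf8, 14.8-fold (6.19 to 46.2), granzyme K (Gzmk), 8.18-fold (3.05 to 30.9), and Cd4, 5.55-fold (2.24 to 17.8). The interferon-inducible Ifi27l2a and Ifitm2 were 5.07-fold (3.52 to 7.53) and 5.17-fold (2.39 to 13.3) higher. Cd4 was at a log2 ratio of 6.35 with the stricter filter in place of 2.41. Igkc, a B cell gene, had 0 and 66 UMIs, 10.9-fold higher against a floor of 3 counts, with a lower interval bound of 8.63-fold. The receptor Klra8 had 56 and 0 UMIs, 37.6-fold lower against a floor of 3 counts, with an upper interval bound of 0.0338-fold. Perforin (Prf1) was at 0.112-fold (0.0546 to 0.213), Irf8 at 0.124-fold, Itgax at 0.149-fold and Klra9 at 0.153-fold (0.0949 to 0.241). Klra8 and Klra9 belong to a family of similar genes, so their split is uncertain. All 56 UMIs of Il12b at 3 months were in 1 cell of 8419 UMIs, the same total as the cell with most Irf8 at that age. Itgax is a marker of monocytes or dendritic cells, whose markers were at 976 and 489 CPM in this class. Itgax was found in 29 of 101 cells at 3 months and 9 of 220 at 24 months, and Irf8 in 35 and 9. The part of monocytes or dendritic cells in the Itgax and Irf8 values is open. The part of the fewer NK-led cells in these values, and in those of Prf1 and Klra9, was not taken apart. The log2 ratio of Irf8 was −2.38 with the stricter filter in place of −2.99. TMM factors moved the median log2 ratio of all genes in this class by 0.11, from 0.01 to 0.12. The interferon list had a median of 0.36 (0.05 to 0.80), 3 of 7 higher and 1 lower, and was at 0.65 with no filter on barcodes. Ribosomal protein genes were at 0.16, 6 of 76 higher, at 0.27 under TMM factors and at 0.10 with the stricter filter. Folding genes were at −0.29 (−0.43 to −0.06), 2 of 13 lower, with Dnajb11 0.567-fold, and at −0.07 with the stricter filter. Mitochondrially encoded genes were at −0.08, which turned to 0.04 under TMM factors and to 0.02 with no filter.

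**Figure D4:**
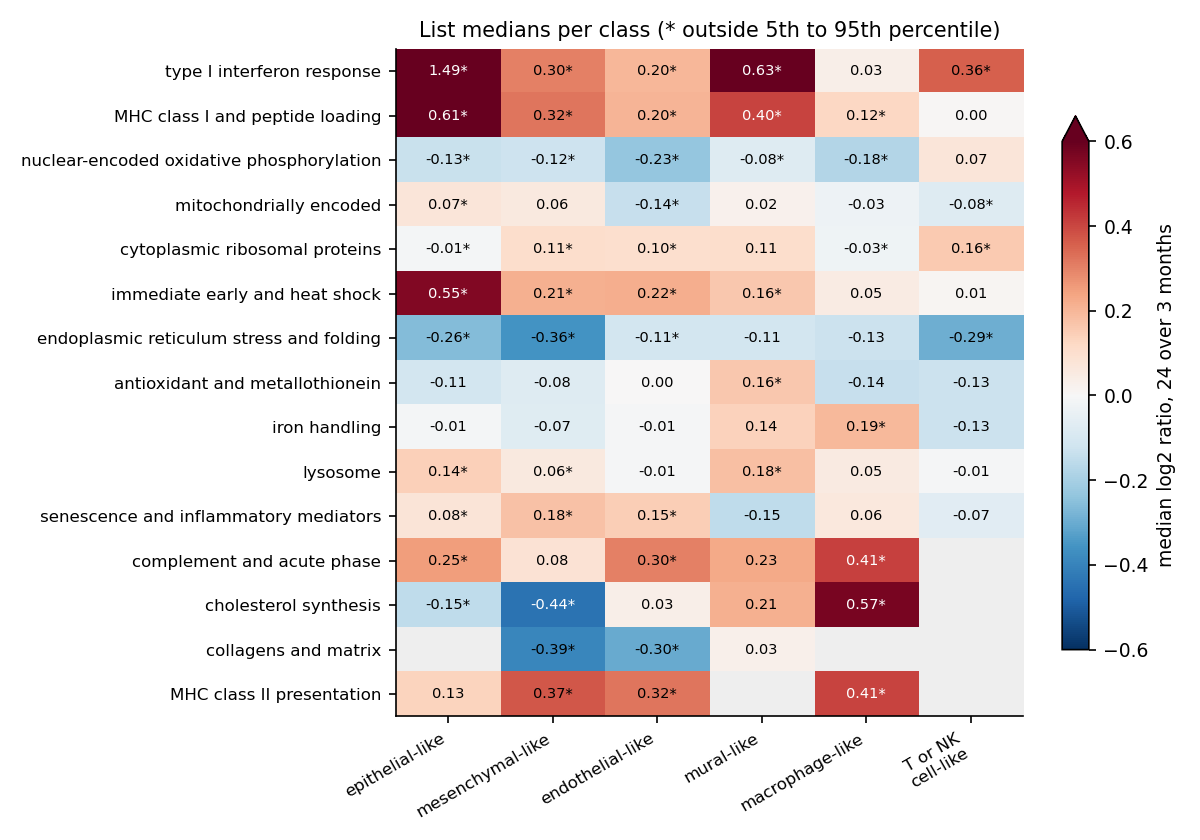
Median log2 ratio of CPM (24 over 3 months, colour and printed value) of the gene lists measured in more than 1 class, with lists as rows, classes as columns, grey for lists with too few genes and a star for medians outside the 5th to 95th percentile of matched random lists. The interferon row runs from 1.49 in epithelial-like to 0.03 in macrophage-like cells and the folding row is at −0.26 in epithelial-like and −0.36 in mesenchymal-like cells; the ribosomal medians of epithelial-like (−0.01) and macrophage-like cells (−0.03) and the mitochondrially encoded median of T or NK cell-like cells (−0.08) turn positive under TMM factors.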

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

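Of the tests in this part, the one of neutrophil markers was chosen before its result was seen, and the one of the macrophage share after the T and B cell shares had been seen.

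Cells outside every named class entered no comparison. Such a cluster was singled out only where its share interval at 24 months lay above that at 3 months. The unnamed cluster held 13 of 8123 kept cells at 3 months and 74 of 9230 at 24 months, 0.160% (0.0852 to 0.274) and 0.802% (0.630 to 1.01), a ratio of 5.01 (2.76 to 9.85). It was led by the cytokine genes Il5, Il13, Csf2 and Ccl1 with Il1rl1, Areg, Calca and the transcription factor Gata3, of which Il5, Il13, Gata3 and the receptor Il1rl1 are genes of type 2 immunity. Its best marker set had 2 markers detected, Ccr2 and Plac8, under the 3 needed for a name, and its median depth was 2170 UMIs.

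The higher shares of T-led cells (ratio 4.36, 3.10 to 6.25) and of B or plasma cell-like cells (ratio 9.02, 3.27 to 34.7) at 24 months were weighed against the preparation. Blood left in the vessels would bring neutrophils with the lymphocytes; barcodes with neutrophil markers were 3 at 3 months and 2 at 24 months, a ratio of 0.585 (0.0489 to 5.11), too few to tell. In endothelial-like cells, however, neutrophil markers were at 6.02 and 66.1 CPM and haemoglobin Hbb-bs at 6.02 and 40.4 CPM, so blood stays open. A lower yield of other cells that raised all immune classes alike would raise the macrophage-like share too. The macrophage-like share had a ratio of 0.809 (0.665 to 0.983), its upper bound below the lower bound of the T-led cluster. Such an even effect of yield alone therefore did not account for the higher T-led share. A yield that differed between immune classes was not tested. More lymphocytes in the plexus with age remains untested, since each age was 1 pooled library and age cannot be told apart from preparation.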

How the results depend on the processing

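With 1 pooled library per age, neither age nor preparation was varied, and these alternatives test only the processing. The alternatives were written before the data were examined, except leaving out epithelial clusters 1, 6 and 7, leaving out mesenchymal cluster 5 and leaving out 1 mesenchymal cell, which were chosen after seeing the data. A value counts as moved when it left the counting interval of the main value, which is narrow in the deep epithelial class. A change of sign counted as a turn only where the main list lay outside matched lists or the interval of the main share difference excluded 0; elsewhere it counted as moved. For single genes, a turn of sign was counted only past the size rule; this was decided after Enpp2 and Folr1, near a ratio of 1, were seen to turn with the scaling. Of the values for the epithelial lists fixed as most important and the shares, 51 moved, 4 turned and 116 stayed. Of the others, 359 moved, 9 turned and 2148 stayed. No paired analysis was possible because each age had 1 library. Where no reason is given, the cause was not tested.

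With the stricter filter, whose limit of 10% mitochondrial UMIs lies below the epithelial medians of 12.4% and 13.5% and so removes most epithelial-like cells, the differences in share were −6.28 percentage points for epithelial-like cells (main 0.257), −4.996 for endothelial-like (−3.08), 6.40 for mesenchymal-like (3.21), 0.533 for T or NK cell-like (1.14) and 0.659 for B or plasma cell-like (0.395). Membership changed too: a cluster of 271 and 457 cells with 9 mesenchymal markers lost its name, and the endothelial and mural cluster (137 and 108 cells) was named endothelial-like. Epithelial medians were −0.0070 for secreted products (main −0.0201), 0.0388 for transport (−0.0294), 0.0942 for junctions (0.0394), 2.00 for interferon (1.49), 0.74 for MHC class I (0.61), −0.16 for oxidative phosphorylation (−0.13) and 0.0448 for mitochondrially encoded genes (0.0718). Ifnb1 in macrophage-like cells turned from −1.59 to 0.18. With no filter, the epithelial mitochondrially encoded median was 0.0764, and that of T or NK cell-like cells turned from −0.0755 to 0.0168. Without doublet removal, the epithelial medians were −0.14 for oxidative phosphorylation and −0.0234 for ribosomal proteins (−0.0114). With each library clustered on its own, the mesenchymal share difference was −4.80, and the mesenchymal lysosomal median turned from 0.0583 to −0.0522. Both set unlike parts of the class against each other, since a 24 month cluster of 742 cells with 8 mesenchymal markers lost its name there.

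Without epithelial clusters 1, 6 and 7, the medians were −0.0699 for transport, 0.58 for interferon, 0.44 for MHC class I, −0.14 for oxidative phosphorylation, 0.13 for mitochondrially encoded and −0.0368 for ribosomal protein genes. TMM factors, the median of ratios and CPM without Ttr and mitochondrial genes move the median over all epithelial genes from −0.0333 to −0.0038, 0 and −0.0040. In that order, they gave 0.0154, 0.0201 and 0.0158 for secreted products, 0.0060, 0.0107 and 0.0064 for transport, −0.20, −0.19 and −0.20 for cilia (main −0.23), −0.0970, −0.0924 and −0.0967 for oxidative phosphorylation, 0.11, 0.11 and 0.11 for mitochondrially encoded genes, and 0.0240, 0.0287 and 0.0245 for ribosomal proteins. CPM without Ttr and mitochondrial genes gave 1.73 for interferon. TMM factors turned mitochondrially encoded genes of T or NK cell-like cells to 0.0365. Ribosomal proteins of macrophage-like cells turned from −0.0261 to 0.0076 under TMM factors and 0.0223 under the median of ratios.

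The mean of per-cell CPM gave epithelial medians of −0.0065 for secreted products, 0.0804 for junctions, −0.14 for oxidative phosphorylation, 0.13 for mitochondrially encoded genes and −0.0013 for ribosomal proteins. Thinned cells gave 1.74 for interferon, −0.125 for oxidative phosphorylation and −0.0024 for ribosomal proteins. A pseudocount of 10 CPM, which shrinks low genes by construction, gave −0.16 for cilia, 0.61 for interferon and 0.19 for MHC class I. Genes with at least 500 UMIs gave 1.90 for interferon and turned mural oxidative phosphorylation from −0.0767 to 0.0650. Leaving out genes 10 times higher in another class gave 1.92 for interferon and 0.16 for MHC class I, and turned the mesenchymal lysosomal median to −0.0053. With no gene filter, cholesterol genes of macrophage-like cells turned from 0.57 to −0.13.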

Other observations

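Some single genes of the fixed lists, chosen here after their values were seen, differed although their list as a whole lay among matched lists. In epithelial-like cells the secreted antioxidant enzyme Gpx3 was 2.15-fold and transferrin (Trf) 1.94-fold higher at 24 months. In mesenchymal-like cells the complement genes C4b and C1s1 were 1.98-fold and 1.78-fold higher. In endothelial-like cells von Willebrand factor (Vwf) was 2.09-fold and angiopoietin 2 (Angpt2) 1.90-fold higher, and in macrophage-like cells the cathepsin Ctsd was 1.55-fold and Apoe 1.31-fold higher. All immune cells with the unnamed cluster were 4.79% (4.33 to 5.28) and 6.23% (5.75 to 6.74) of kept cells.

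The tests in the paragraphs that follow were chosen after the result each bears on had been seen. The bounds for the clock test were set after its values were seen, and the wording of the test of another class's RNA was rewritten after a first run.

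Interferon genes higher in epithelial-like cells could come from RNA or cells of another class. This was excluded, since the closest class, mesenchymal-like cells, had its markers at 162 and 164 CPM, 0.0788% of the increase needed. The case of 1 responding mouse of 4, giving an equal share of cells, was weighed by the share of cells with few interferon UMIs. That share would then have stayed at 0.75 or more of its value at 3 months. It was 0.336 of that value (upper bound 0.383). The bound of 0.75 assumes that cells of the other mice carried no RNA of the responding one. Their tissue was pooled before digestion, so this case is not excluded. Other numbers of responding mice, or unequal shares of cells, were not tested. A different mix of ventricles in the pools is not weighed in this text. Age, housing, infection or preparation of 1 pooled library may each underlie the response and cannot be told apart here.

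Several clock-controlled genes were lower at 24 months, which could come from dissection at another time of day. The set was not compared with matched lists. In epithelial-like cells Per3, Tef, Nr1d1 and Bhlhe41 were lower by the size rule. Dbp, Hlf and Ciart were below 1 but short of that rule, and the intervals of Per1, Per2 and Nr1d2 included 1. The median of the Per, Dbp and Nr1d genes was −0.27 in epithelial-like, −0.34 in endothelial-like and −0.47 in mesenchymal-like cells, so the highest of the 3 was −0.27. Arntl, Npas2 and Clock, which peak in the opposite phase, had medians of 0.19, 0.03 and 0.52, the endothelial one from 1 gene, so the shift of phase was undecided. In mural-like cells the Per set was at −0.62, with 6 of 6 ratios below 1. Of these, the intervals of Per1, Per2 and Nr1d2 included 1. The other set was Clock alone, at 0.632-fold (0.317 to 1.19), too few counts to tell. The time of dissection is not given in the sources used here.

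Haemoglobin Hbb-bs was higher at 24 months in several classes, at 13.9 and 28.3 CPM in epithelial-like, 40.4 against 6.02 in endothelial-like, 27.0 against 2.79 in macrophage-like and 10.6 against 2.59 in mesenchymal-like cells. The test of blood stayed undecided.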
